A study of Homo sapiens with 8 samples.

How the data were processed

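Total RNA from rBC2LCN-positive and rBC2LCN-negative PC-3 cells was labelled with Cy3 and hybridised to SurePrint G3 Human GE arrays, 1 sample per array, per the labels' protocols. The deposited scanner files hold the spot intensity written by Agilent Feature Extraction 11.5.1.1, per the file headers. Per the file headers, that software subtracted background and spatial trends to give the processed intensity, and nothing was scaled between arrays at that step. The authors also deposited a table of log2 values of the same arrays. Its scale, centring and direction were found by setting each column against the processed intensity of its array. Each column was log2 of the processed signal minus the array's 75th percentile, with slopes between 1.0004 and 1.0007 and correlations across probes between 0.99987 and 0.99994. Its column medians lay between −3.38 and −3.22, and genes were not centred. That table served as an alternative.

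Each array held 62976 spots, of which 4259 control spots were left out, and 42405 distinct probes. Spots carrying an outlier flag on an array were dropped there, no spot was saturated, and spots of a probe were averaged. The files name probes by accession. RefSeq transcript accessions, compared without versions, were turned into symbols with a RefSeq gene table of assembly GRCh38.p14. This named 26910 probes with 20108 symbols, and 15495 probes kept the file's accession. The files' probe annotation uses hg19, so no coordinate of the table was used, only names and the order of neighbouring genes. The main values were log2 of the processed signal minus the array's 75th percentile over probes. A probe was kept if it was well above background on all 4 arrays of at least 1 group (23204 probes), and 125 of these were dropped because every spot was flagged on some array. The brightest probe stood for each gene, which left 18591 genes, 13371 of them named. Among called genes, 753 had other tested probes, and 6 genes had another probe called in the opposite direction (PTPRN2, PNKD, MDM1, EPB41L5, CYBRD1 and FAM199X).

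Groups, replicate numbers and passages came from the sample labels. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without a block), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The interaction of group with passage pair and the difference between passage pairs were fitted over the same 8 arrays. A gene with no probe well above background on any array of a group has only a bound there. The bound is the mean of the brighter group minus the mean of, per array, the higher of the lowest signal among probes well above background and the gene's own signal, on the normalized log2 scale. It is written as at least N-fold. Log2 fold changes are rBC2LCN-positive minus rBC2LCN-negative, and an SE is limma's moderated standard error.

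The lists of genes, 34 in all, were written down before the data were examined, as were the main fits, their alternatives and the rule for named genes. That rule took the 12 largest increases and the 12 largest decreases among called genes with the same direction in all 4 pairs and a proper symbol, the 4 members of smallest p of each list, a fixed set that included FUT1, FUT2, PODXL, CD44, PROM1, ALDH1A1, CD24, EPCAM, POU5F1, SOX2, NANOG, MYC, CDH1, VIM, ZEB1, TP63 and MKI67, and called genes of the interaction and passage fits, of which there were none. MMP9, DST, CLDN1, CLDN3, PKP2, CDH2, SNAI2 and FN1 fall outside the rule and were named after their values were seen, to say which list members went the other way or did not pass. The untested members TNF, IL1A, CCL2, CXCL10, CSF3, CCL20, KRT5, NGFR, KRT6B and COL17A1 were also named after the data were seen. Lists were tested with limma's camera with a preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the 34 lists. Normexp background correction (offset 50) used the median spot signal and the median local background, in place of the mean spot signal that had been planned, and that alternative is to be read with this change.

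The replicate numbers pair the samples. In the labels both samples of a number carry the same passage, and the deviations of same-numbered arrays from their group means correlated by 0.620, 0.183, 0.306 and 0.420 across genes, all above the limit of 0.1. The main fit had no block, as fixed before the data were examined, and the replicate block was an alternative. Other alternatives were quantile normalization, median scaling, no filter on dim probes, a filter over all 8 arrays, the mean of a gene's probes, all probes singly, the replicate number as a random block, slide as a block, each slide alone, eBayes with trend and robust options, the authors' log2 table, and each array or passage pair left out.

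The fits were tested on simulated arrays with the 18591 genes' real means and spreads and 200 changed genes. For the comparison of positive with negative cells, 65.7% of genes changed by 1 on the log2 scale were recovered, 94.0% of those changed by 2 and 95.5% of those changed by 3, with 10 false calls. For the interaction with passage pair, 1.49%, 49.3% and 72.7% were recovered, and for the passage pair 67.2%, 97.0% and 100%. Of 20 simulated lists of 25 genes, the 5 shifted by 1 on the log2 scale were called, and no other list was. These simulations give genes no correlation with each other, and arrays of the same passage none either. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

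A processed intensity close to background gives an unsure fold change, and the 75th percentile sets all changes relative to the brighter part of the array. The median log2 fold change of all tested genes was 0.01 with this scaling. An array shows relative and not absolute amounts of a transcript.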

Results

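Gene expression was measured in PC-3, a human prostate cancer cell line derived from a bone metastasis, after live cells had been sorted by their binding of rBC2LCN. rBC2LCN is a recombinant lectin that binds glycans ending in an H-type fucose structure, and here it carried a far-red dye. The 8 samples formed 2 groups, with 4 rBC2LCN-positive and 4 rBC2LCN-negative samples, each on its own single-colour array. Replicates 1, 2, 3 and 4 came from passages 33, 34, 29 and 30, and each passage gave 1 positive and 1 negative sample. The labels do not say whether the passages were separate cultures, so the p-values measure the spread between these samples. The 75th percentile of the probe signal lay between 688 and 941 scanner units per array, and 52.8% to 64.4% of the probes were well above background. With 4 arrays per group, the number of arrays limits the precision. The comparison asks how cells that bind the lectin differ in expression from cells that do not, in a series whose title links binding to stem-like behaviour.

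The rBC2LCN-positive cells had higher levels of 35 of 38 genes of epithelial identity, among them CDH1 and EPCAM, and of the fucosyltransferase gene FUT1. They had lower levels of ZEB1 and VIM, and of 8 of 21 genes of mesenchymal identity, while 2 others of that list were higher. Of 18591 tested genes, 3649 differed at an adjusted p threshold of 0.05 (limma), 1761 of them higher and 1888 lower in the positive cells. A difference of at least 2-fold was found for 1500 of these genes, 837 higher and 663 lower, and for 979 genes with normexp background correction. The direction was the same in all 4 pairs of arrays from 1 passage for 3635 of the 3649 genes. These genes were called from the same arrays, which favours such agreement, so the count is not an independent replication. Arrays of the same group correlated across genes with r between 0.974 and 0.992, and arrays of different groups with r between 0.946 and 0.969. The first principal component held 61.0% of the variance and separated the groups, and the second held 17.6% and set the pair of passage 33 apart. With the passage as a replicate block 5654 genes were called, of which 3531 were also called without it. Passages 33 and 34 were on slide 1 and passages 29 and 30 on slide 2, so slide and passage cannot be told apart. With slide as a block 4225 genes were called. Within slide 1 alone, with 2 arrays per group, 476 genes were called, 73.3% of them higher in the positive cells, and within slide 2 alone 1480, 51.5% of them higher. Among the same tested genes, 515 of 516 called on slide 1 and 1703 of 1719 called on slide 2 had the same direction on the other slide. Without the passage 33 pair 4377 genes were called, and without the pair of passage 34, 29 or 30 in turn 1829, 2410 and 1646.

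Among named genes with the same direction in all 4 pairs, the 12 largest increases in positive cells included those of MAL, a membrane protein of apical sorting, and LCN2, an iron-binding secreted protein. MAL stood at 4.13 ± 0.38 in positive and −1.58 ± 1.15 in negative cells (log2 signal relative to the array's 75th percentile, mean ± SD, n = 4), a 52.5-fold difference with an adjusted p of 0.000125. LCN2 was 51.5-fold higher (log2 fold change 5.69 ± 0.39 SE). UCA1, a long non-coding RNA, was 34.0-fold higher, the protease gene KLK6 32.0-fold and LAD1, which encodes a basement membrane anchoring protein, 30.2-fold. The other genes of this set were well above background on only some negative arrays. CYP1B1, a cytochrome P450 gene, was 52.9-fold higher with 2 negative arrays above background, and MACC1 46.1-fold higher with 1. BSPRY, ATP2C2, the calprotectin gene S100A9, the epithelial transcription factor gene OVOL1 and the interleukin-1 receptor antagonist gene IL1RN were between 34.0-fold and 42.1-fold higher, each with 3 negative arrays above background.

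In the other direction, GBX2, a homeobox gene, was 17.9-fold lower in positive cells (2.72 ± 0.27 in negative and −1.44 ± 0.50 in positive cells, mean ± SD, n = 4), and CRABP1, a retinoic acid binding protein gene, was 18.9-fold lower. FAM20A, NAP1L3, ZNF711 and PDGFRA were not well above background on any positive array. Their levels were at least 15.4-fold, 7.61-fold, 5.45-fold and 4.38-fold lower there, with adjusted p values between 3.13e-06 and 0.00310. GABBR2 and C1S, well above background on 2 positive arrays each, were 25.8-fold and 16.8-fold lower. SPARC and NPY1R, well above background on 1 positive array each, were 19.7-fold and 16.8-fold lower. FBXL7 was also lower, but its tested probe was not well above background on any positive array. SPARC varied widely among the negative arrays (SD 1.74 on the log2 scale), as did FAM20A (SD 1.87).

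Of 38 tested genes of epithelial identity, 35 were higher in positive cells and none was lower, and the count adjusted over the list alone was also 35. The median log2 fold change was 2.68, or 2.54 with the 2 members that were dim in negative cells set at their bounds, and 1.77 with normexp background correction. CDH1, the epithelial cadherin, was 14.4-fold higher (3.85 ± 0.32 SE, adjusted p 8.38e-05) and EPCAM, a surface protein of epithelia, 8.04-fold. CDH3, EHF and ST14 were 11.7-fold, 12.4-fold and 12.5-fold higher, EHF with 3 negative arrays above background. MARVELD3, a tight junction gene, was at least 6.63-fold higher. The 3 members that did not pass were the claudin genes CLDN3 (log2 fold change 0.25) and CLDN1 (−0.23) and the desmosome gene PKP2 (−0.03). The list shifted against all other genes (camera, adjusted p = 6.16e-29 with a preset correlation), but that call was lost with an estimated correlation (adjusted p = 0.0976). The mean level of the list was 0.01 and −0.03 in the negative arrays of passages 33 and 34 and 0.55 and 0.45 in those of passages 29 and 30, against 2.66 to 2.90 in the positive arrays. Its median log2 fold change was 2.84 within slide 1 and 2.46 within slide 2, and with slide as a block the adjusted p was 6.69e-27.

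Of 21 tested genes of mesenchymal identity, 8 were lower in positive cells and 2 were higher, and 10 passed when adjusted over the list alone. ZEB1, a repressor of epithelial genes, was 6.86-fold lower (−2.78 ± 0.14 SE, adjusted p 9.40e-06), and VIM, the intermediate filament of mesenchymal cells, was 2.75-fold lower. The collagen gene COL5A1 was 4.34-fold lower. The 2 higher members were ACTA2, a smooth muscle actin, which was 2.64-fold higher with 3 negative arrays above background, and MMP9, a matrix metalloproteinase. CDH2 (log2 fold change 0.10), SNAI2 (0.14) and FN1 (−0.76) did not pass. The median log2 fold change was −0.19 (camera, adjusted p = 0.0128, and adjusted p = 0.149 with an estimated correlation), and the call was lost with the replicate block (adjusted p = 0.0536) and without negative replicate 3 (adjusted p = 0.0520). The median was −0.11 without positive replicate 2 and also without positive replicate 3. With slide as a block the camera adjusted p was 0.0287. With probes filtered anew within each slide, the median was −0.25 within slide 1 (camera, adjusted p = 0.0596) and −0.35 within slide 2 (camera, adjusted p = 0.00960). Over the same 21 genes the medians were −0.27 on slide 1 and −0.24 on slide 2.

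**Figure D1:**
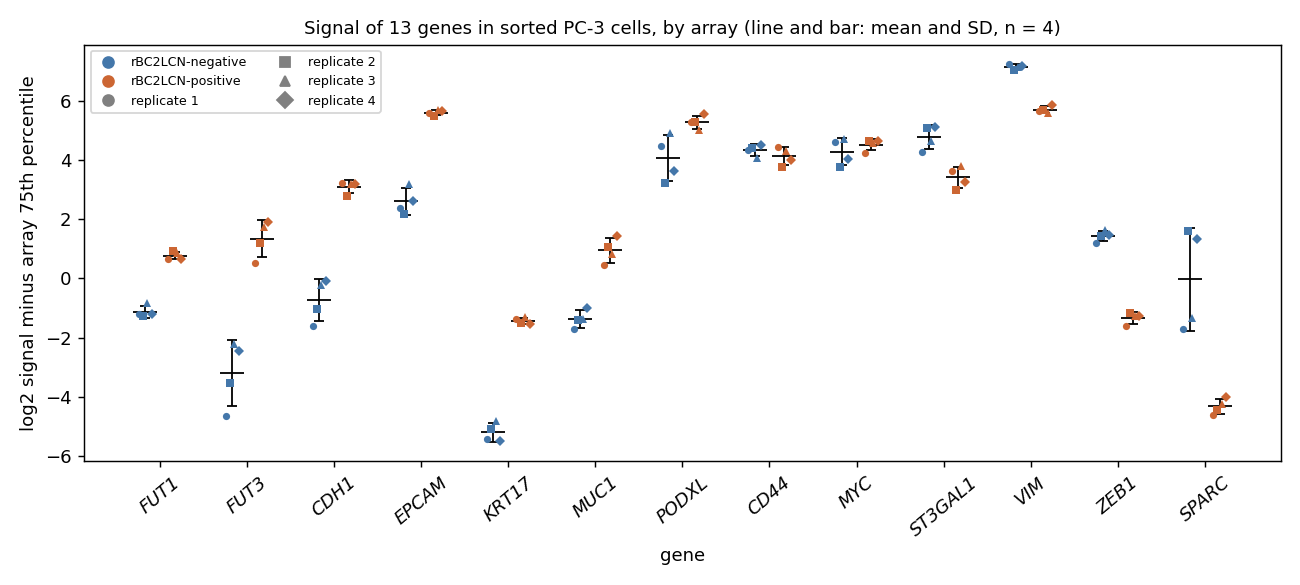
Each point is the signal of 1 array (log2, minus that array's 75th percentile) for 13 named genes, with rBC2LCN-negative arrays in blue, rBC2LCN-positive arrays in orange and the marker shape giving the replicate; lines and bars are the mean and SD of 4 arrays. The groups do not overlap for FUT1, CDH1, EPCAM, VIM or ZEB1, while CD44 and MYC overlap; FUT3 was well above background on 3 negative arrays, KRT17 on 1 negative array and SPARC on 1 positive array.

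Among 11 tested genes of prostate basal cells, 8 were higher in positive cells and 1 was lower, and 10 passed when adjusted over the list alone. The keratin genes KRT17 and KRT14 were 13.7-fold and 16.3-fold higher, each with 1 negative array above background, and KRT6A was at least 6.51-fold higher. KRT6A has near-identical relatives that its probe may also detect. S100A2 was 5.09-fold higher (7.44 ± 0.10 against 5.09 ± 0.23, mean ± SD, n = 4). The lower member was DST, which links keratin filaments to hemidesmosomes, at a log2 fold change of −0.29 (adjusted p 0.0433). With the mean of its probes DST was reversed and not called (0.29, adjusted p 0.166). The list's median log2 fold change was 2.35 (camera, adjusted p = 1.37e-07, and adjusted p = 0.0976 with an estimated correlation), with 2.52 within slide 1, 2.17 within slide 2 and an adjusted p of 6.39e-07 with slide as a block. TP63, the basal transcription factor, was not well above background on any array. The same held for the basal keratin gene KRT5 and for NGFR. KRT6B and COL17A1 were well above background on 2 arrays each, so none of these 4 genes was tested either. Of 10 tested genes of prostate luminal cells, 1 was higher and 2 were lower (4 adjusted over the list alone; camera, adjusted p = 0.991), and with the replicate block 3 were higher and 2 lower. HOXB13, a prostate lineage homeobox gene, was 6.02-fold lower in positive cells, FOLH1, which encodes prostate-specific membrane antigen, was also lower with its tested probe above background on no positive array, and NDRG1 was 2.44-fold higher.

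Genes for the glycans that the lectin binds went both ways. FUT1, which encodes the transferase that adds the terminal fucose of the H antigen, was 3.75-fold higher in positive cells (0.78 ± 0.14 against −1.13 ± 0.21, mean ± SD, n = 4; adjusted p 3.48e-05), in all 4 pairs. FUT2, the other gene of that activity, was not well above background on any array. Of 16 tested genes of H-type glycan synthesis, 5 were higher and 4 lower (10 adjusted over the list alone), and the list did not pass against other genes (camera, adjusted p = 0.514), and 3 of the 4 pairs had a list median under 0. Its own genes passed in fry with an adjusted p of 4.75e-07 for changes in either direction and 0.0198 for 1 direction. B3GNT3, a chain-extending enzyme gene, was 3.60-fold higher and GALNT3, which starts O-glycans, 3.27-fold higher, while B3GALT1 was at least 2.57-fold lower. Among 8 other fucosyltransferase genes, FUT3, which makes Lewis antigens, was 23.6-fold higher with 3 negative arrays above background, and FUT8, the core fucosyltransferase, and POFUT2 were 1.63-fold and 1.46-fold lower (4 adjusted over the list alone; camera, adjusted p = 0.486). The FUT3 probe may also detect its close relatives. Of 11 genes of GDP-fucose supply and fucose removal, FUCA2 was 1.52-fold higher, PMM2 1.35-fold higher and PMM1 1.34-fold lower (4 adjusted over the list alone; camera, adjusted p = 0.498).

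Of 15 tested sialyltransferase and sialic acid supply genes, 2 were higher and 4 lower (9 adjusted over the list alone; camera, adjusted p = 0.486). ST6GALNAC1 was 7.73-fold higher with 2 negative arrays above background. ST3GAL1, ST3GAL2 and ST3GAL3, whose products cap galactose with sialic acid, were 2.59-fold, 2.08-fold and 1.81-fold lower. Among 8 mucin and sialomucin genes, 4 were higher and 2 lower (6 adjusted over the list alone; camera, adjusted p = 0.229). MUC1 was 5.01-fold higher and MUC5B 2.24-fold higher, and CD164 and PODXL2 were 1.88-fold and 1.87-fold lower. PODXL, which encodes podocalyxin, a known carrier of rBC2LCN ligands on pluripotent stem cells, was 2.33-fold higher (1.22 ± 0.34 SE, adjusted p 0.0368), a call that was lost with the replicate block (adjusted p 0.0547) and median scaling (adjusted p 0.0519). It was also lost without any 1 array other than negative replicates 1 and 3 (adjusted p from 0.0614 without positive replicate 3 to 0.10 without negative replicate 4).

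Of 19 tested markers used for cancer stem cells, 8 were higher and 3 lower in positive cells (14 adjusted over the list alone; 10 higher and 6 lower with the replicate block). The list's median log2 fold change was 0.52 and was above 0 in all 4 pairs. The list did not pass against other genes (camera, adjusted p = 0.104), while its own genes moved 1 way on balance (fry, adjusted p = 0.000848). ITGA2, the collagen-binding integrin subunit, was 2.81-fold higher (1.49 ± 0.09 SE), and the epithelial gene EPCAM, described above, belongs to this list too. CXCR4, a chemokine receptor, was at least 5.22-fold lower. CD44 had a log2 fold change of −0.21 ± 0.17 (SE, adjusted p 0.462) and CD24 one of 0.65 ± 0.21 (adjusted p 0.0624, 0.0319 with the replicate block and 0.0244 without negative replicate 4). PROM1 was not well above background on any array, and ALDH1A1 was so on 3 of the 8. Of 10 tested pluripotency genes, TFCP2L1 passed, 2.87-fold higher with 3 negative arrays above background (1 adjusted over the list alone; camera, adjusted p = 0.225). With the replicate block 4 of the 10 passed, all of them higher. POU5F1 (−0.14 ± 0.23, adjusted p 0.742) and MYC (0.24 ± 0.22, adjusted p 0.519) did not pass. SOX2 was not well above background on any array and NANOG was so on 3.

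The list of NF-kB cytokines and chemokines also holds genes of other kinds, among them all those named as higher here. Of its 24 tested genes, 11 were higher in positive cells and none was lower (13 adjusted over the list alone). Besides LCN2 they included C3, the central complement component, 9.69-fold higher with 2 negative arrays above background, and TNFAIP2, 4.41-fold higher. PTGS2, the inducible prostaglandin synthase, was at least 4.08-fold higher. Untested members were TNF and IL1A, well above background on no array, CCL2 on 1, CXCL10 on 2, CSF3 on 4 and CCL20 on 6. The list's median log2 fold change was 0.56 (camera, adjusted p = 4.94e-07, adjusted p = 0.267 with an estimated correlation, and adjusted p = 2.86e-06 with slide as a block). With probes filtered anew within each slide, its median was 0.65 within slide 1 and 0.54 within slide 2. Over the same 24 genes it was 0.66 on slide 1 and 0.47 on slide 2. For this list 2 of 35 splits of the arrays into equal sides, the real one among them, gave a camera p as small. Chance was thus not excluded for its shift. No list's camera call held with an estimated correlation. Correlation alone does not account for that loss. The mesenchymal list's estimated correlation (−0.0272) lay under the preset 0.01, yet its camera adjusted p rose from 0.0128 to 0.149. The loss of a call there is therefore not by itself evidence against a list's shift. With limma's fry, which tests whether a list's genes move without comparing them with other genes, 19 of 34 lists passed for a move in 1 direction on balance and 27 for changes in either direction.

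**Figure D2:**
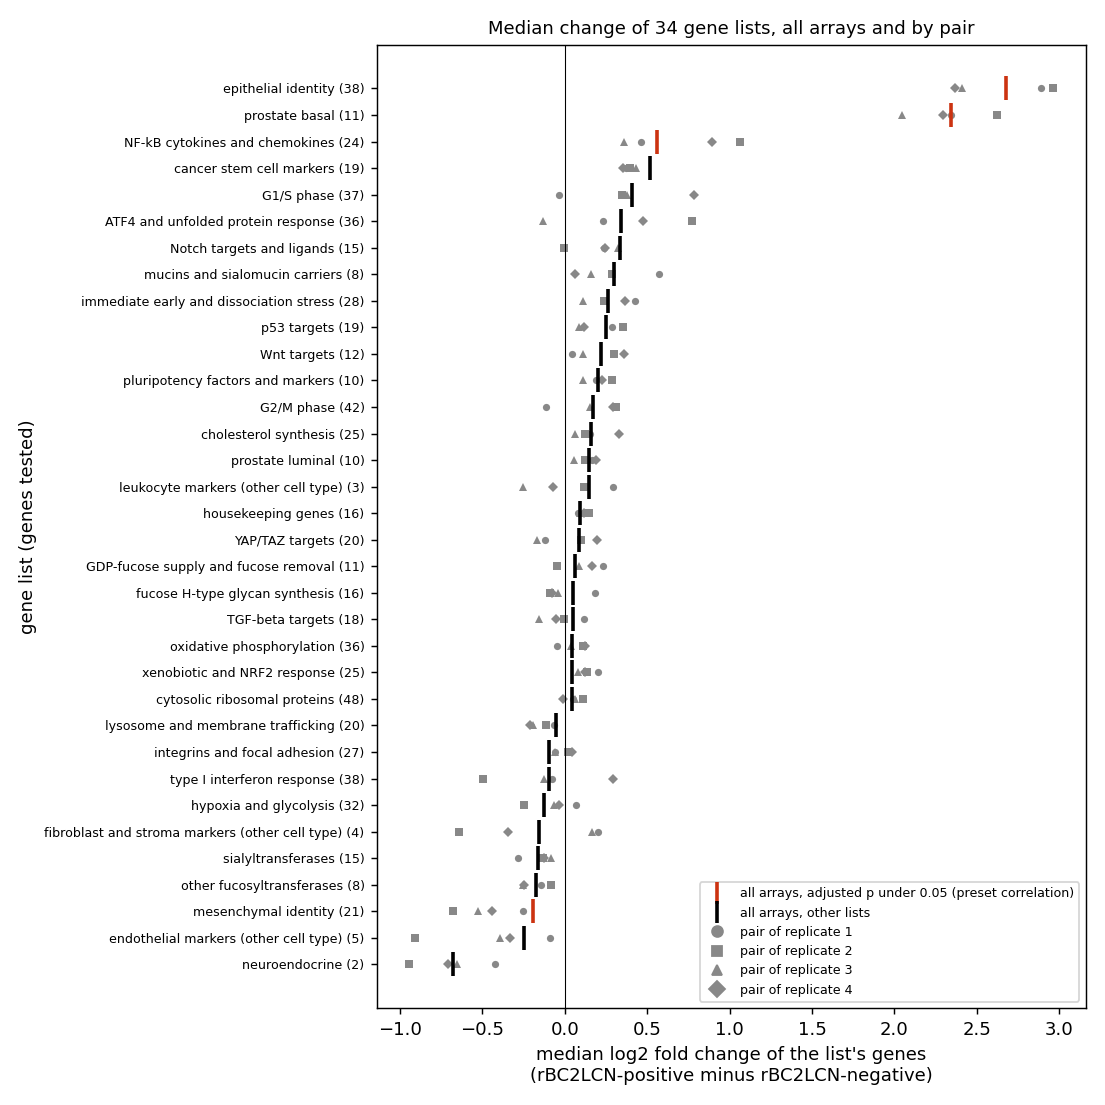
Each row is 1 of 34 gene lists with its number of tested genes, the vertical bar is the median log2 fold change (positive minus negative) over all 8 arrays, and the grey markers are the medians within each of the 4 passage pairs. The epithelial and prostate basal lists have medians above 2 in all 4 pairs, and the red bars are the 4 lists past an adjusted p of 0.05 with a preset correlation.

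Cell cycle genes stood highest in both arrays of passage 33, and 8 G1/S genes and 8 G2/M genes differed between the sorted groups with the replicate block, against 1 of each without it. Of 37 genes of G1/S phase, CCNE1, the cyclin of S phase entry, passed (1.89-fold higher; 0 adjusted over the list alone), and MCM4, a replicative helicase gene, had a log2 fold change of 1.12 ± 0.43 (SE, adjusted p 0.109, and 0.00533 with the replicate block). The list's mean level was 2.47 in both arrays of passage 33 and between 0.37 and 1.57 in the other arrays. Its median log2 fold change was 0.41 (camera, adjusted p = 0.0788), which passed with the replicate block (adjusted p = 5.41e-05), with slide as a block (adjusted p = 0.0243) and within slide 2 (adjusted p = 5.47e-09), but not within slide 1 (median 0.21, adjusted p = 0.378) or with an estimated correlation (adjusted p = 0.846). The list's median was under 0 in 1 of the 4 pairs. The 8 G1/S genes that passed with the replicate block were all higher. Of 42 genes of G2/M phase, CDC25B passed, 1.83-fold lower, and with the replicate block 7 were higher and 1 lower (1 adjusted over the list alone; camera, adjusted p = 0.343). MKI67, a proliferation marker, had a log2 fold change of 0.17 ± 0.43 (SE, adjusted p 0.832).

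Several signalling lists held large changes in both directions or in a few members. Of 15 Notch genes, 4 were higher and 2 lower (7 adjusted over the list alone; camera, adjusted p = 0.104; 6 higher and 2 lower with the replicate block), with the receptor gene NOTCH3 14.4-fold higher, LFNG 3.61-fold, the ligand genes JAG2 3.27-fold and DLL1 at least 3.16-fold higher. Of 12 Wnt targets, 3 were higher and 1 lower (4 adjusted over the list alone; camera, adjusted p = 0.104), among them ASCL2 at least 5.01-fold and NKD2 3.17-fold higher, LEF1 at least 1.94-fold higher and AXIN2 at least 3.0-fold lower. Of 19 p53 targets, 5 were higher and none lower (5 higher and 2 lower adjusted over the list alone; camera, adjusted p = 0.104), and with the replicate block 7 were higher and 1 lower. The death receptor gene FAS was 4.39-fold higher, PHLDA3 2.64-fold, the cell cycle inhibitor gene CDKN1A 4.13-fold and PLK3 1.98-fold, FAS with 3 negative arrays above background and CDKN1A with 2. Of 20 YAP/TAZ targets, 3 were higher and 5 lower (9 adjusted over the list alone; camera, adjusted p = 0.912): CCN2, a matricellular protein gene, was 3.84-fold lower and NT5E 4.39-fold lower, while F3, the tissue factor gene, was 5.09-fold higher and ANKRD1 16.2-fold higher with 3 and 1 negative arrays above background. Of 18 TGF-beta targets, 3 were higher and 5 lower (10 adjusted over the list alone; camera, adjusted p = 0.912; 6 higher and 6 lower with the replicate block), with THBS1 6.14-fold and LTBP2 3.72-fold higher, LTBP2 with 2 negative arrays above background, and ID2 4.22-fold lower.

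Of 27 integrin and focal adhesion genes, 9 were higher and 6 lower (16 adjusted over the list alone; camera, adjusted p = 0.498). ITGB2, an integrin subunit of leukocytes, was 4.26-fold higher, the caveolin gene CAV2 3.87-fold and LAMA3, a laminin of epithelial basement membranes, 3.35-fold. Of 28 immediate early and dissociation stress genes, 5 were higher and 2 lower (7 adjusted over the list alone; camera, adjusted p = 0.139; 10 higher and 2 lower with the replicate block), with ATF3 2.90-fold, ZFP36 2.22-fold and DUSP1 1.95-fold higher. Of 32 hypoxia and glycolysis genes, 6 were higher and none lower (6 adjusted over the list alone), but the list's median log2 fold change was −0.13 (camera, adjusted p = 0.719). With the replicate block 9 hypoxia and glycolysis genes were higher and 5 lower. The mean of this list was positive at 0.09, and the median and mean also had opposite signs for the luminal, other fucosyltransferase and integrin lists. The direction of the camera test was opposite to the median for the hypoxia, integrin, YAP/TAZ and TGF-beta lists. ERO1A, ADM, VEGFA and SLC2A1 were 2.16-fold, 2.01-fold, 2.19-fold and 1.70-fold higher. Of 25 xenobiotic and NRF2 response genes, 5 were higher and none lower (5 adjusted over the list alone; camera, adjusted p = 0.178; 5 higher and 2 lower with the replicate block), including the reductase genes AKR1B10, 11.2-fold, AKR1B1, 3.93-fold, and GSR, 1.46-fold. The AKR1B10 probe may also detect a close relative.

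Of 25 cholesterol synthesis genes, 4 were higher and none lower (4 adjusted over the list alone; camera, adjusted p = 0.0620). Of 36 ATF4 and unfolded protein response genes, ATF3 and DNAJC3 were higher, DNAJC3 by 2.02-fold (1 adjusted over the list alone; camera, adjusted p = 0.104), and with the replicate block 7 were higher and 1 lower. Of 38 interferon response genes, OASL and IFIH1 were 2.64-fold and 2.42-fold higher and UBE2L6 1.75-fold lower (2 adjusted over the list alone; camera, adjusted p = 0.931), and with the replicate block 6 were higher and 3 lower. Of 20 lysosome and trafficking genes, 3 were higher, NPC2 by 1.70-fold, and 2 lower, the protease gene CTSB by 2.02-fold (5 adjusted over the list alone; camera, adjusted p = 0.498), and with the replicate block 4 were higher and 7 lower. RPS3 was the single ribosomal protein gene of 48 that passed, 1.24-fold higher (0 adjusted over the list alone; camera, adjusted p = 0.318), and it did not pass with median scaling (adjusted p 0.0623) or quantile normalization (adjusted p 0.109). ATP5F1D was the single oxidative phosphorylation gene of 36, 1.44-fold higher (0 adjusted over the list alone; camera, adjusted p = 0.471), and with the replicate block 3 were higher and 1 lower. Of 16 housekeeping genes, 2 were higher and none lower (1 lower with the replicate block), GUSB by 1.38-fold (2 adjusted over the list alone; camera, adjusted p = 0.431).

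Markers of other cell types that a culture or gate could hold were mostly below background. Of the tested fibroblast and stroma markers, 4 in all, PDGFRA was lower and ACTA2 higher (2 adjusted over the list alone; camera, adjusted p = 0.507), and both also stand in the mesenchymal list. Of 5 tested endothelial markers, KDR, a receptor of vascular endothelial growth factor, was at least 3.43-fold lower in positive cells (1 adjusted over the list alone; camera, adjusted p = 0.431), and with the replicate block 2 were lower. None of 3 leukocyte markers passed over all genes or when adjusted over the list alone (0; camera, adjusted p = 0.912). Neither of 2 neuroendocrine markers, ENO2 (−0.72) and TUBB3 (−0.64), passed over all genes, and 1 did so when adjusted over the list alone (camera, adjusted p = 0.318). With the replicate block both passed (adjusted p 0.0124 and 0.00721).

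The passages allowed a second question, whether the difference between positive and negative cells changed from passages 29 and 30 to passages 33 and 34. No gene passed for that interaction (limma; 171 genes at an unadjusted p under 0.05, 0.920% of those tested against the 5% of chance). That fit leaves the differences between passages of a pair in its error. With the replicate block no gene passed either (limma; 399 genes at an unadjusted p under 0.05, 2.15% of those tested). No gene passed between passages 33 and 34 and passages 29 and 30 over both groups either (limma, smallest adjusted p 0.166). At an unadjusted p under 0.05 that passage fit gave 3600 genes, 19.4% of those tested. The fit counted the 2 arrays of each passage as independent, although same-numbered arrays correlated. With 2 passages per side, the 5% of chance is therefore not a fair measure for it. With normexp background correction 2 genes passed for the passage difference, IRS2, which encodes an insulin receptor substrate (−1.12 on the log2 scale, passages 33 and 34 minus 29 and 30, adjusted p 0.0361) and CCDC177 (1.1, adjusted p 0.0361). These 2 genes were chosen after their values were seen. Passage and slide cannot be told apart in this comparison.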

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

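The test with array quality as a covariate was chosen after the quality measures had been seen, the splits of single lists and the count of lists over splits balanced for the sort after the count of lists and the lists' own p had been seen, and the carry-over test and the test of each slide's calls on the other slide after the patterns had been seen. In all, 358 sets of 4 values (named genes, list levels and array measures within a group) were searched for a value far from the other 3, and 19 sets (5.31%) held such a value, where chance flags about 1 set in 20.

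On the log2 scale, relative to the array's 75th percentile, negative replicate 1 (passage 33) stood apart in B3GNT3 (1.62 against 2.07 to 2.10), CDH3 (−1.11 against −0.68 to −0.64), ZFP36 (0.32 against 1.21 to 1.39) and JAG2 (−0.78 against −1.99 to −1.83). Negative replicate 3 stood apart in FUT1 (−0.82 against −1.28 to −1.20) and CLDN3 (3.72 against 4.26 to 4.34). Positive replicate 1 stood apart in ATP2C2 (1.36 against 1.69 to 1.75), LTBP2 (−2.97 against −2.86 to −2.84), TUBB3 (2.80 against 1.48 to 1.51) and MYC (4.24 against 4.60 to 4.65). Positive replicate 2 stood apart in CDH1 (2.78 against 3.20 to 3.23), ASCL2 (−2.57 against −2.46 to −2.45), KDR (−3.46 against −6.49 to −6.31, none well above background), and in the mean levels of the mucin list (0.84 against 1.00 to 1.02) and the integrin list (2.36 against 2.47 to 2.49). Positive replicate 3 stood apart in PHLDA3 (2.933 against 3.004 to 3.016) and the p53 target list (0.53 against 0.37 to 0.38). Positive replicate 4 stood apart in ERO1A (3.75 against 3.44 to 3.48) and the list of GDP-fucose supply (1.345 against 1.254 to 1.268).

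The number of genes that differed between positive and negative cells was weighed against technical explanations. Only 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, gave as many called genes (3649, against at most 2 in any other split and 0 in the others that parted all 4 pairs). The other splits held the sort difference in their error, which lowers their counts. Only 8 splits part all 4 pairs, too few for a share under 0.05 that respects the pairing. The real split stood far above the others, but this count alone cannot exclude chance. The split that follows the slides gave 0 genes, but the sort difference stood in its error, so that count decides nothing about slide. Each slide held 2 arrays of each group. Of the genes called on slide 2 alone 99.1% had the same sign on slide 1 (99.8% for those called on slide 1 alone), which argues against slide or scan day. With array quality measures as covariates in turn, 76.8% to 94.2% of the called genes stayed called, which argues against the measured quality as the whole cause (smallest exact permutation p of a quality measure between groups 0.171, too little to exclude a difference). Of the 3649 genes, 3531 were also called with the replicate block. Together with the agreement between slides, this argues against chance for these samples. The arrays thus show a difference in expression between the sorted fractions. Its cause was not tested, and the labels do not say whether the passages were separate cultures.

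For the gene lists chance was not excluded as a count: 33 of the 35 splits gave as many called lists as the real one (4, against 10 in the highest other split, which called 0 genes, parted 2 pairs and held 3 arrays of 1 sorted group on each side, so it carried part of the sort). Of the 18 splits with 2 arrays of each sorted group per side, 16 gave as many called lists as the real one, and the highest gave 7, so lists were also called where the sort was balanced. What those calls came from was not tested. The estimated correlation between genes was far above the preset 0.01 in some lists. It was 0.956 for G1/S, 0.909 for G2/M, 0.733 for interferon response and 0.61 for ribosomal protein genes. The epithelial list had 0.225, and others such as the mesenchymal list (−0.0272) lay under 0. For lists with a high correlation the camera p with the preset value is too small. Taken singly, the epithelial list had its smallest camera p in the real split, in 1 of 35 splits (1.81e-30, against 2.87e-19 in the next), and so had the prostate basal list, 1 of 35 (8.03e-09 against 2.41e-06), and the mesenchymal list, 1 of 35 (0.00150 against 0.00314), although 13 of 35 splits gave the mesenchymal list a median as large. For the NF-kB list 2 of 35 splits gave a p as small (4.36e-08, against 2.59e-08 in another split), so chance was not excluded there. These 4 lists were chosen by their camera p in the real split. Ranking first therefore does not exclude chance for the epithelial, prostate basal and mesenchymal lists either. For the passage comparison the 18 splits with 2 arrays of each group per side are too few for a share under 0.05, and the real split gave 0 genes and the highest other 8. At an unadjusted p under 0.05 the order was the other way, as the real split had 3600 genes, the most of the 18, and the highest other 2645. The splits that kept both arrays of each passage on 1 side gave 3600 (the real one), 2645 and 317 genes. These are too few splits to rank the real one.

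The epithelial list stood higher in the negative arrays of passages 29 and 30 (0.55 and 0.45) than in those of passages 33 and 34 (0.01 and −0.03). Carried-over positive cells could raise such genes in a negative sort. The 172 genes at least 8-fold higher in positive cells limit the carried-over share to 4.21% and 2.98% of the positive level in these arrays (5th percentile of their ratios). The excess over the passage 33 and 34 arrays lay above that limit for 47.4% of the 38 list members in both arrays (exact 95% interval 31.0% to 64.2%), an interval that includes a share of 50%, so carried-over cells and a real difference between passages cannot be told apart here. The difference falls together with slide, and no test separates those.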

How the results depend on the processing

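The list tests by slide, with median scaling and with the replicate block and an estimated correlation were chosen after the data were seen. The 3649 genes called between positive and negative cells became 3343 to 3717 with quantile normalization, median scaling or normexp, 3059 with probes above background on all 8 arrays, and 3628 with the authors' log2 table, which shared 3605 genes. They became 5654 with the replicate block, the paired fit, and 6515 with the replicate number as a random block. They became 2308 of 34260 genes with no filter on dim probes, 1500 with a fold change of at least 2 required, and 476 on slide 1 only and 1480 on slide 2 only, where fewer arrays entered. Leaving out arrays gave 1646 to 4377 genes. The count moved by over 1.5 times without both arrays of replicate 4 (1646), replicate 2 (1829) or replicate 3 (2410), and without any 1 array it stayed between 2522 and 4307. The 4 called lists became 9 with no filter on dim probes, 0 with an estimated correlation, and 0 with an estimated correlation and the replicate block. With both of these, even the epithelial list had a camera adjusted p of 0.666, so that count decides nothing about a list's shift. Without 1 array, 4 to 7 lists were called, 7 without positive replicate 2, where cholesterol synthesis, immediate early and Notch genes were added (adjusted p = 0.0392 each). Cholesterol synthesis was also added without negative replicate 2 or positive replicate 3 (adjusted p = 0.0248 and 0.0211). The ATF4 list was added without positive replicate 1, negative replicate 3 or negative replicate 4 (adjusted p = 0.00108, 0.0320 and 0.0403). The G1/S list was added without negative replicate 1 (median 0.80 in place of 0.41, adjusted p = 7.93e-07), positive replicate 3 or positive replicate 4 (0.0277 and 0.0138), and the G2/M list without negative replicate 1 (0.000142). The epithelial, prostate basal and NF-kB lists kept their direction and call in every alternative run with a preset correlation. The interaction gave 0 genes in every alternative run, and the passage comparison gave 0 except with normexp, which gave 2. Of 4377 values of 170 named genes under the alternatives, 3943 kept their direction and side of the threshold, 333 lost a call, 100 gained 1, and DST was reversed with the mean of its probes (0.2948). Among 133 genes in the text the replicate block changed the call of PODXL, CD24, MCM4, ENO2, TUBB3 and IRS2 alone (IRS2 adjusted p 0.00173 between positive and negative cells). Where fewer arrays or another number of genes does not show it, the cause was not tested. Signal over background limits the fold changes of 43 of the 170 named genes, which were not well above background on all 8 arrays.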

Other observations

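The tests of gene families and of neighbouring genes were chosen after the data were seen. Keratin genes as a family were higher in positive cells: of 27 tested, 16 were higher and 0 lower (camera over 219 families of gene symbols, adjusted p = 1.52e-08, and adjusted p = 0.0725 with an estimated correlation). The named members of families were chosen after their values were seen. Beyond KRT14, KRT17 and KRT6A these included KRT4 (2.72 ± 0.23 on the log2 scale, SE, with 2 negative arrays above background), KRT7 (1.86 ± 0.39) and KRT8 and KRT18, the pair of simple epithelia (1.54 ± 0.11 and 0.87 ± 0.10). Of the 27, 9 belong to the fixed lists, and keratin pseudogenes, whose probes may also detect the keratin genes, are among the 16. The family's median was between 0.89 and 1.03 over the main and 4 other scalings or background corrections.

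Genes for intraflagellar transport, the traffic that builds cilia, were lower in positive cells, 6 of 16 and none higher (camera, adjusted p = 0.0315, and adjusted p = 0.980 with an estimated correlation). IFT81 had a log2 fold change of −1.09 ± 0.17 (SE) and IFT27 one of −0.61 ± 0.14. Of 392 zinc finger genes with the symbol ZNF, 77 were lower and 10 higher (camera, adjusted p = 0.00141, and adjusted p = 0.923 with an estimated correlation). Outside the runs of neighbouring genes described next, 46 of 302 were lower and 7 higher. These directions held with quantile normalization, median scaling, normexp and the authors' log2 table.

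Neighbouring genes shifted together in 12 runs along the genome, 6 lower and 6 higher in positive cells, which held 1070 of 13356 ordered genes and 380 of their 3053 called genes. The lowest run reached from SCML2 to CXCR3, with 119 of 156 genes lower (median log2 fold change −0.40, −0.38 on slide 1 and −0.41 on slide 2). The runs with the next lowest mean over 50 neighbouring genes went from TMEM238 to CENPBD2P (56 of 78 genes lower) and from SERF1B to PGGT1B (94 of 113), and the run with the highest such mean from BRAF to DNAJB6 (65 of 82 genes higher, median 0.32). Random gene orders argue against chance (permutation p = 0.001, the smallest that 1000 orders can give). The other tests used the lowest run found on every second gene and the 74 genes left out between them. The left-out genes had a median of −0.44, outside the central range of left-out genes matched on brightness (−0.09 to 0.10), which argues against brightness. Without strongly changed genes their median was −0.417 (67 genes), which argues against a few strong genes. A candidate explanation is a difference in copy number between the cells in the sorted fractions. Of the left-out genes, 75.7% were lower (exact 95% interval 64.3% to 84.9%, against 49.1% of all left-out genes), as copy number would need. The other 5 runs found on every second gene varied, as 70.4% to 77.5% of the left-out genes were lower in the 3 lower runs and 25% and 37.2% in the 2 higher runs. The intervals of 2 of these 5 runs, 49.8% to 86.2% and 23.0% to 53.3%, reached close to or past the share over all left-out genes, so the support for copy number is not uniform across runs. Regulation of whole regions would give the same values and was not tested. Of the 3649 called genes 3269 lay outside the runs or had no place in the order, and 1 of 38 epithelial list members lay inside a run.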
